A study of Homo sapiens with 9 samples.

How the data were processed

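RNA was sequenced from MNT-1 cells, a human cutaneous melanoma line, that carried a control hairpin or 1 of 2 hairpins against ABCB6 (shABCB6 1 and shABCB6 2), with 3 libraries per group and 9 in all, per the labels. The labels name the Illumina TruSeq RNA kit, and give neither the strand of the libraries nor whether the replicates were separate cultures. CASAVA, HISAT and HTSeq 0.6.0 were used with the genome build GRCh38, per the submitters' processing notes. Each library has a table with an expected count and an FPKM value per gene, per the file headers. The deposited expected counts are not scaled, and 75.7% to 77.3% of those above 0 in a library are exactly whole numbers as deposited, with no tolerance; the tool that made these fractional counts is not stated, since HTSeq gives whole ones. The deposited FPKM values are scaled by the authors to gene length and library size, and were used only for the level of ABCB6. A series table named as raw counts holds FPKM, per the file headers, and all its values match those of the single libraries (0 differ by more than 0.005); it was not used further.

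The expected counts were rounded to whole numbers, and a gene not listed for a library was given a count of 0. Library totals ran from 8595575 to 9266633, and 16600 to 17322 genes were listed per library. Of 21041 genes listed in any library, 13673 passed the edgeR filter on low counts (filterByExpr by group, a count of about 10 in 3 libraries) and were tested. CPM were computed from these counts with trimmed mean (TMM) normalization. Genes were kept by identifier; 495 symbols belong to more than 1 tested identifier, 1221 identifiers in all, many of them alternate-sequence copies, and the split of reads between such copies is uncertain.

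Groups were taken from the labels. All 9 libraries were fitted together with edgeR 4.0.16 (robust quasi-likelihood, R 4.3.3), and 4 comparisons were tested: each hairpin against control, the mean of both hairpins against control, and shABCB6 1 against shABCB6 2. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE of a log2 fold change is its size divided by the square root of the F statistic. The square root of the common dispersion was 0.195. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, adjusted over 21 lists within a comparison; 26 lists were fixed, and 5 with under 5 tested members were described only. The test was repeated with a correlation estimated per list and with fry, without the GC and length correction. The fry test asks whether genes of a list move one way on balance, and does not compare them with other genes. It passed 4, 9, 10 and 0 lists in the 4 comparisons. DESeq2 1.42.0 and limma-voom were run as alternatives, along with other normalizations, filters, a fold minimum, fits on the compared groups alone, a block for the replicate number and each library left out in turn. These choices were made before the data were examined.

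Libraries of a group correlated at 0.956 to 0.98 (Pearson r of log2 CPM across genes), and the chi-square per gene between libraries of a group ran from 4.80 to 57.5, so no library is a copy of another. The first principal component held 51.4% of the variance and parted the groups, and the second, with 15.0%, parted the replicate 1 libraries from the rest. Whether the replicate numbers pair the libraries was checked by the correlation of their deviations from the group means. For libraries of the same number (1, 2 and 3) it was 0.437, 0.213 and 0.137 between shABCB6 1 and control and 0.369, 0.243 and 0.128 between shABCB6 2 and control. The numbers were therefore taken to pair hairpin and control libraries, a pairing that comes from the values and not from the labels. It is uncertain for number 3: control replicate 3 correlated better with replicate 2 of shABCB6 1 (0.170) and of shABCB6 2 (0.198). The fit without a block stays the main one. Transcript GC content, length and base shares came from 1 transcript per gene of GENCODE 29, which 12842 of the tested genes (93.9%) have. After the data showed a trend with GC content and length, a correction was added: in each library a spline of log2 CPM, relative to the mean of all libraries, on GC content and log2 length (4 degrees of freedom each) was entered as an offset in the same fit, which brought the correlation of the log2 fold change with GC content to between -0.06 and 0.03. A fit on replicates 2 and 3 only was added for the same reason.

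The genes named were set by a rule fixed before the data were examined: ABCB6; the 12 highest and 12 lowest shared genes by the smaller of the 2 fold changes; the 5 highest and 5 lowest for each hairpin; the 6 highest and 6 lowest between hairpins; and up to 4 members of each list with the smallest adjusted p, plus pigment and heme genes past the threshold with both hairpins (at most 8 each). Outside the lists these were protein-coding, with a mean of at least 5 CPM and no overlap between the groups compared. For CENPE, with 2 counts in the shABCB6 2 group, the ratio to control is scaled to total counts without the TMM factors and given with an exact binomial interval, which covers counting error only.

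The fits were tested on simulated data for the same genes. With changes of 1.5, 2 and 4-fold in 200 genes, edgeR recovered 14.9%, 53.7% and 90.9% for shABCB6 1 against control with 4 false calls, 13.4%, 53.7% and 89.4% for shABCB6 2 with 5, and 23.9%, 67.2% and 92.4% for both hairpins with 5, and called 0 genes between the hairpins, which had no simulated difference. DESeq2 recovered 31.3%, 61.2% and 92.4% for shABCB6 1 with 21 false calls, and limma-voom 14.9%, 53.7% and 92.4% with 1. When the GC and length trend of the real libraries was added, edgeR made 74, 2916 and 2059 false calls for shABCB6 1, shABCB6 2 and both hairpins. With the correction these were 5, 5 and 6. The added trend was the spline that the correction itself fits, so the correction had to remove it. This does not show that it removes all bias of the real libraries. A list of 30 genes shifted by 0.5 on the log2 scale passed camera (adjusted p = 2.12e-29, and adjusted p = 0.000254 with an estimated correlation), and 0 of 20 unshifted lists did.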

Results

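ABCB6 mRNA was lower in all 6 libraries with a hairpin against ABCB6 than in the 3 libraries with the control hairpin. ABCB6 encodes an ATP-binding cassette transporter and lies on chromosome 2, from 219209766 to 219219017 in GRCh38. The control libraries held 101, 109 and 129.9 CPM (counts scaled to library size), the shABCB6 1 libraries 53, 55.2 and 62.9 CPM, and the shABCB6 2 libraries 26.3, 18.2 and 19.7 CPM. The means were 113 ± 14.9 CPM (SD, n = 3), 57 ± 5.22 CPM (SD, n = 3) and 21.4 ± 4.27 CPM (SD, n = 3), so that 50.3% of the control level was left with shABCB6 1 and 18.9% with shABCB6 2. In the deposited FPKM values the means were 45.4 ± 6.41, 21.8 ± 1.24 and 7.88 ± 1.45 (SD, n = 3 each). The log2 fold change was -0.99 ± 0.16 (SE) for shABCB6 1 (edgeR adjusted p = 0.00275) and -2.40 ± 0.17 (SE) for shABCB6 2 (adjusted p = 4.6e-06). The hairpins differed from each other by 1.41 ± 0.17 (SE, adjusted p = 0.00728). No library went against its label on this gene.

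**Figure D1:**
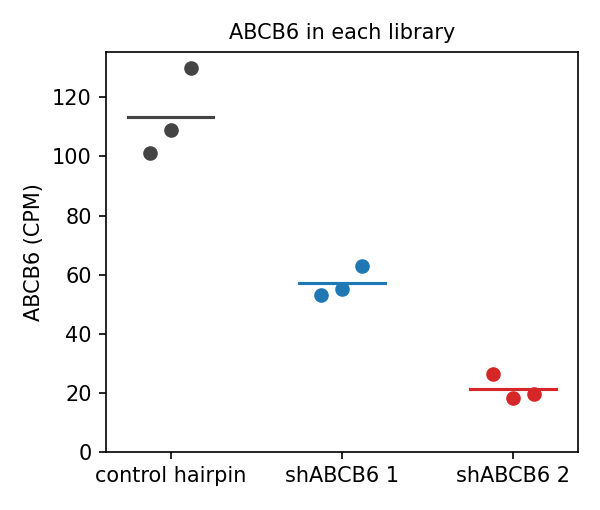
ABCB6 in CPM (y axis) in each library of the control hairpin, shABCB6 1 and shABCB6 2 groups (x axis), with points for the 3 libraries of a group and a line for their mean. All control libraries lie above 101 CPM and all hairpin libraries below 63 CPM.

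The labels do not say that the replicates of a group were separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

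A large set of genes differed from control in the same direction with both hairpins. Their changes followed base composition, as given below, and a bias of the libraries stays open for them as a set. Of 13673 genes tested, 747 rose and 1199 fell past the threshold with both hairpins, and 1 gene, MAPK4, passed it in opposite directions. Among genes of at least 5 CPM on average, the strongest shared falls included CENPF of the centromere, TPR of the nuclear pore, GOLGA4 of the Golgi and EEA1 of endosomes. The strongest shared rises among these genes included RAP1GAP, NSG1 and RXRG; over all genes past the threshold, the largest log2 fold change over both hairpins was 6.58 and the lowest -7.63. Independent lists of these sizes would share 164 rising and 261 falling genes. The log2 fold changes of the hairpins correlated across genes (Pearson r = 0.867, genes not being independent replicates), with a covariance of 0.508 and the same sign in 86.4% of genes. Both comparisons use the same control libraries, and in 20 simulated data sets with no effect and shared controls the mean correlation was 0.478, the mean covariance 0.0649 and the share with the same sign 66.5%, while no gene passed with both hairpins. The covariance exceeded the simulated one by 0.443. The 3 control libraries cannot be split into independent sets of at least 2 for each hairpin, so part of the excess may come from the shared controls. The simulated sets also held no GC and length trend and no effect of the replicate number. They therefore do not show what overlap or covariance these would give without a hairpin effect. Library size without a composition factor gave 383 shared rises and 1532 shared falls, 3115 genes were shared with the replicate number as a block, and 726 genes were shared without control replicate 3 and 771 without control replicate 2.

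**Figure D2:**
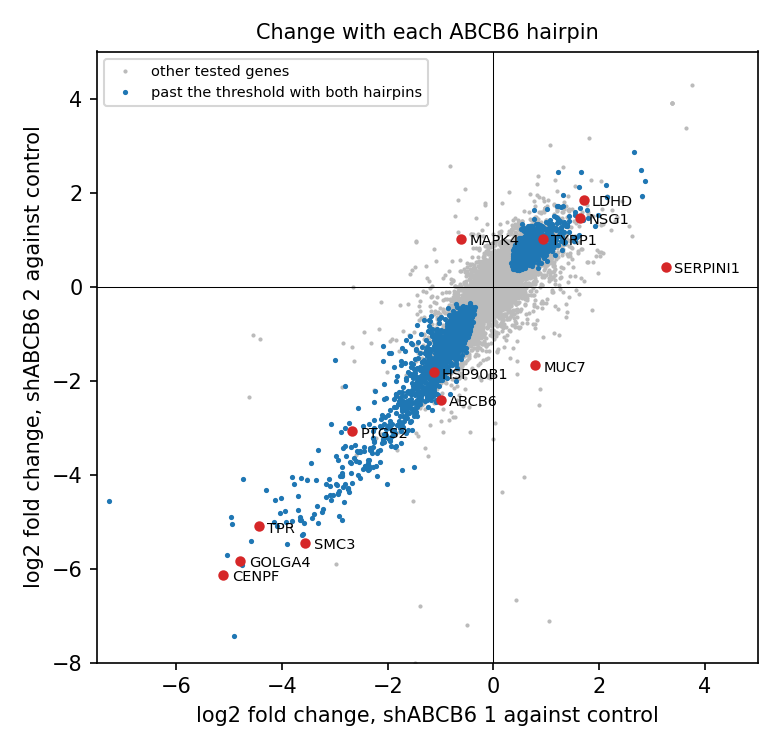
Log2 fold change against control of each tested gene with shABCB6 1 (x axis) and shABCB6 2 (y axis), with the genes past the threshold with both hairpins in blue, other genes in grey and named genes in red. The blue points hold 1199 shared falls and 747 shared rises; genes beyond the axis limits are not drawn.

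In what follows, a value beside a gene is its log2 fold change over both hairpins against control unless another unit or comparison is given. The named genes with the strongest shared fall had every hairpin library below every control library, which the rule for naming them required. Those with a reference transcript were rich in A, from 34.1% of bases in PPIG to 41.4% in CENPE. The median was 31.2% in all shared falls with a reference transcript. A bias on A content therefore stays open for these named genes, and values after the A content correction are not given for single genes. CENPF, a centromere protein of dividing cells, fell from 182 ± 92.7 CPM (SD, n = 3) to 5.24 ± 0.351 CPM with shABCB6 1 and 2.57 ± 0.535 CPM with shABCB6 2, a log2 fold change of -5.62 ± 0.31 (SE) over both hairpins (adjusted p = 1.28e-06). CENPE, a kinesin that moves chromosomes, had 445 counts over the control libraries, 14 with shABCB6 1 and 2 with shABCB6 2; scaled to total counts without the TMM factors, its level with shABCB6 2 was 0.429% of control (95% binomial interval 0.0518% to 1.56%, which covers counting error only). KIF20B, a kinesin of cell division, fell with -5.35 (adjusted p = 6.5e-06). The chromatin protein gene HMGN5 fell with -5.00 (adjusted p = 2.14e-06). GOLGA4 of the Golgi, KTN1 of the endoplasmic reticulum and EEA1 of early endosomes fell with -5.32 ± 0.25 (SE), -4.44 ± 0.21 and -4.59 ± 0.33. TPR, a protein of the nuclear pore basket, fell with -4.77 (adjusted p = 8.18e-07), and the translation initiation factor gene EIF5B with -4.34 (adjusted p = 1.55e-07). PPIG, which encodes a cyclophilin with a serine and arginine rich domain, fell with -4.31, and UACA with -4.58. BDP1, a subunit of an RNA polymerase III initiation factor, fell with -5.00; this identifier is an alternate-sequence copy, as are those of FBL, HLA-C and 1 of the BAG6 entries below. For genes with several identifiers, such as RPS9 and HLA-C, or with close copies, such as the GAGE genes, reads can be assigned to the wrong one.

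Among the named shared rises, GAGE12F, a cancer-testis antigen gene, had a log2 fold change of 2.15 ± 0.43 (SE, adjusted p = 0.00388), and GAGE12J of the same family 1.51 ± 0.33 (adjusted p = 0.0054). RAP1GAP, which inactivates the GTPase RAP1, rose from 10.6 ± 3.4 CPM (SD, n = 3) to 32.8 ± 3.09 CPM and 33.6 ± 4.24 CPM (log2 fold change 1.65, adjusted p = 1.65e-04). The lactate dehydrogenase D gene LDHD rose by 1.77 (adjusted p = 0.00148), the nuclear receptor gene RXRG by 1.75 (adjusted p = 0.00165), and NSG1, a neuronal vesicle protein gene, by 1.56 (adjusted p = 2.8e-05). The basement membrane gene NID1 rose by 1.63 ± 0.26 (SE), the galectin-3-binding protein gene LGALS3BP by 1.32 ± 0.23, AIF1L by 1.42, TMEM229B by 1.47 and ENHO by 1.35. An identifier of FBL, the fibrillarin gene, rose by 1.56 (adjusted p = 0.0124).

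The changes moved with the base composition of the transcripts. Across 12842 genes with a reference transcript, the log2 fold change against control correlated with transcript GC content (Spearman rho 0.534 for shABCB6 1 and 0.644 for shABCB6 2) and with transcript length (-0.316 and -0.383). In single libraries the Spearman correlation, across genes, of log2 CPM relative to the mean of all libraries with GC content ran from -0.587 to -0.43 in control libraries, from -0.261 to 0.316 with shABCB6 1 and from 0.409 to 0.62 with shABCB6 2. The median GC content was 40.6% in shared falls, 58.0% in shared rises and 48.4% in all genes tested. With a correction for GC content and length, chosen after the data were seen, 541 genes rose and 877 fell with both hairpins; 716 of 1173 falls (61.0%) and 213 of 706 rises (30.2%) stayed past the threshold with both. With the replicate number as a block too, 1151 rose and 1274 fell with both. ABCB6 kept its fall, with -1.26 for shABCB6 1 and -2.86 for shABCB6 2. CENPF had -4.92 and NSG1 1.35 after the correction. When the A content of the transcript was added to the correction, also after the data were seen, 1042 genes were shared, 609 of them lower with both hairpins.

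**Figure D3:**
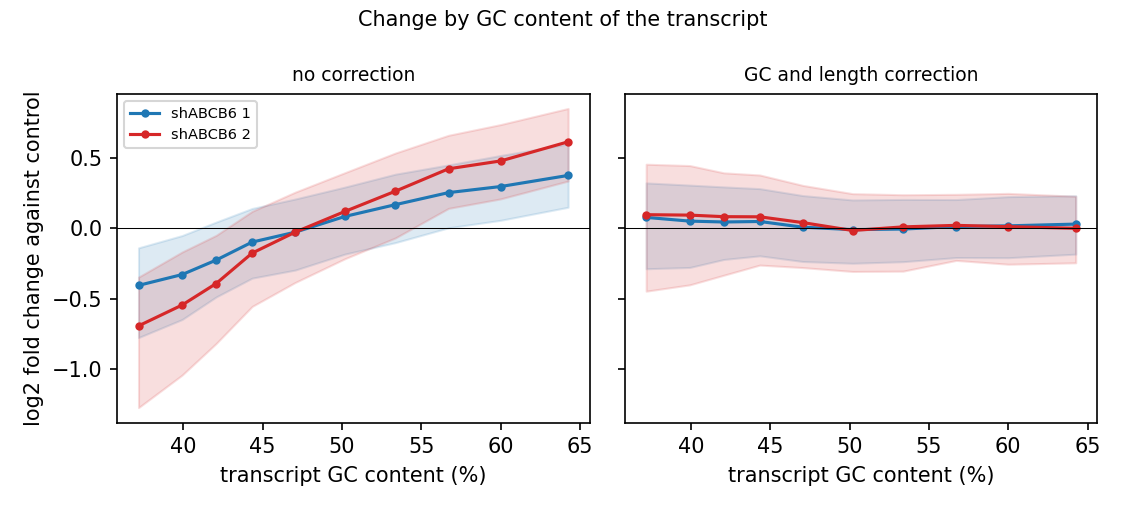
Median log2 fold change against control (y axis; shading from the lower to the upper quartile) of genes in 10 equal groups of transcript GC content (x axis, %) for shABCB6 1 and shABCB6 2, without (left) and with (right) the correction. Without it, the 10% of genes lowest in GC content had a median of -0.40 and -0.69, and the highest 10% had 0.38 and 0.61.

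shABCB6 1 against control gave 2095 genes, 828 higher and 1267 lower, of which 776 had an absolute log2 fold change of at least 1. Of the 2095, 2087 had no overlap between hairpin and control libraries; 5509 of all tested genes had none, where chance gives 10%. SERPINI1, which encodes neuroserpin, rose most among the named genes, from 2.37 ± 0.407 CPM (SD, n = 3) to 23 ± 4.43 CPM (log2 fold change 3.27 ± 0.22 (SE), adjusted p = 1.74e-05). The cell adhesion gene SDK2 rose by 2.57 (adjusted p = 0.015), GAGE12F by 2.14, RXRG by 1.99 and NID1 by 1.80. CENPF, HMGN5, CENPE, GOLGA4 and KIF20B were the lowest of the named genes, at -5.11, -4.95, -4.91, -4.79 and -4.76. The GC and length correction gave 1654 genes, 671 higher and 983 lower. Library size without a composition factor gave 475 higher and 1595 lower and moved the median log2 fold change by -0.10. Without control replicate 3 the count was 767, without control replicate 2 it was 811, and with the replicate number as a block it was 3424.

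shABCB6 2 against control gave 5516 genes, 2704 higher and 2812 lower, with 1824 at an absolute log2 fold change of at least 1. Of the 5516, 5411 had no overlap with control, as did 7281 of all tested genes, where chance gives 10%. ADGRG1, an adhesion G protein-coupled receptor gene, rose by 2.44 ± 0.36 (SE, adjusted p = 5.68e-04). An identifier of the ribosomal protein gene RPS9 rose by 1.95 (adjusted p = 3.89e-04) and SLX1B, a nuclease subunit gene with a close copy, by 1.90 (adjusted p = 0.031); SLX1B was at 1.05 after the GC and length correction (adjusted p = 0.195) and missed the threshold with the replicate number as a block (adjusted p = 0.0981). GAGE12F and LDHD rose by 2.16 and 1.84. CENPF fell with -6.13, KIF20B with -5.93, GOLGA4 with -5.84 and RBM25, a splicing factor gene, with -5.48 ± 0.24 (SE, adjusted p = 9.14e-07). The correction gave 3357 genes, 1679 higher and 1678 lower. Library size without a composition factor gave 1485 higher and 3789 lower and moved the median by -0.19, and without control replicate 3 the count was 3586.

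Taking both hairpins together against control, 5081 genes passed, 2407 higher and 2674 lower, and 1277 of them had an absolute log2 fold change of at least 1. The GC and length correction gave 3306, 1596 higher and 1710 lower. Library size without a composition factor gave 1377 higher and 3547 lower, with a median shift of -0.14. Leaving out control replicate 3 gave 2829 genes and leaving out control replicate 2 gave 2909. The gene lists below were fixed before the data were examined and are described in this comparison. Of 21 lists tested, 6 passed with a preset correlation of 0.01 between genes and 0 with an estimated correlation (lowest adjusted p = 0.821), and 3 passed after the correction for GC content and length. In a fit of 2 groups the real split gave 5 lists, and 62 of 84 splits of the 9 libraries, the real one included, gave at least as many. With the replicate number as a block 9 lists passed, 3 of them not called in the main fit: heme and porphyrin genes (adjusted p = 0.0429), mitochondrially encoded mRNAs (adjusted p = 0.0211) and extracellular matrix and adhesion genes (adjusted p = 0.0429), each with an adjusted p = 0.694 with an estimated correlation.

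Pigment genes moved both ways. Of 36 melanosome and pigment genes measured, 11 rose, 5 fell and 20 did not pass (adjusted over the list alone, 11 and 5), and the list was not called (adjusted p = 0.35). TYRP1, a melanin synthesis enzyme, rose by 0.98 ± 0.13 (SE, adjusted p = 2.76e-04) and the melanosome fibril gene PMEL by 0.67 ± 0.12 (adjusted p = 0.00162). HPS6 and BLOC1S1, subunits of complexes that build lysosome-related organelles, rose by 0.75 and 0.69. BLOC1S6 of the same machinery fell with -0.67, the adaptor subunit gene AP3B1 with -0.56 and the copper transporter gene ATP7A with -0.59. After the GC and length correction 7 members were higher and 0 lower (list adjusted p = 0.0622). Adding the replicate number as a block gave the list an adjusted p = 0.0449, and adjusted p = 0.418 with an estimated correlation. TYRP1 was at 1.35 (adjusted p = 1.93e-06) and PMEL at 0.41 (adjusted p = 0.0151) after the correction. AP3B1 was at 0.08 (adjusted p = 0.678), ATP7A at 0.13 (adjusted p = 0.577), HPS6 at 0.28 (adjusted p = 0.0851), BLOC1S1 at 0.21 (adjusted p = 0.163) and BLOC1S6 at -0.15 (adjusted p = 0.245). Of 23 melanocyte lineage regulators, 5 rose, 7 fell and 11 did not pass (adjusted over the list alone, 5 and 7); the list was not called (adjusted p = 0.948), with a median of 0.14 and a mean of -0.04. The survival gene BCL2A1 fell with -1.23 ± 0.18 (SE, adjusted p = 5.94e-04), the ion channel gene TRPM1 with -0.78 and MITF, the melanocyte transcription factor, with -0.66 ± 0.10 (adjusted p = 6.72e-04), while TBX2 rose by 0.58. The correction left 3 higher and 3 lower; BCL2A1 was at -1.04 (adjusted p = 5.87e-04), and MITF at -0.20 (adjusted p = 0.0859), no longer past the threshold. Of 12 dedifferentiated or invasive melanoma genes, AKR1B1 and LOXL2 rose by 0.47 and 0.84, TEAD1 fell with -0.72 and 9 did not pass (list adjusted p = 0.562; adjusted over the list alone, 0 and 1); 0 rose and 0 fell after the correction.

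The heme, iron and ATP-binding cassette lists were not called by camera in the main fit, while fry passed all 3 (adjusted p = 0.0164, 0.0268 and 0.00151). A pass in fry does not set a list apart, since it is not compared with other genes and 37.2% of all tested genes passed. After the GC and length correction camera gave adjusted p = 0.392 for the heme list and 0.874 for the ATP-binding cassette list. Of 24 heme and porphyrin genes, 8 rose, 2 fell and 14 did not pass (adjusted p of the list = 0.0638; adjusted over the list alone, 8 and 2). BLVRB, which reduces biliverdin, rose by 0.93 ± 0.12 (SE, adjusted p = 2.33e-04), the mitochondrial outer membrane protein gene TSPO by 0.90, the heme transporter gene SLC48A1 by 1.08, the heme oxygenase gene HMOX1 by 0.91 (adjusted p = 0.00761) and the uroporphyrinogen synthase gene UROS by 0.58. The heme exporter gene FLVCR1 fell with -0.94 (adjusted p = 4.9e-04). After the correction 3 were higher and 1 lower, with BLVRB at 0.29 (adjusted p = 0.0608), UROS at 0.52 (adjusted p = 0.00529) and FLVCR1 at -0.52 (adjusted p = 0.022). Of 21 iron handling genes, 5 rose, 3 fell and 13 did not pass (list adjusted p = 0.35; adjusted over the list alone, 5 and 3). The ferritin genes FTH1 and FTL rose by 0.89 ± 0.13 (SE) and 0.76 ± 0.13, and the metal transporter gene SLC39A14 by 0.39. The correction left 5 higher and 2 lower (list adjusted p = 0.0622). The list passed when the correction was joined by the replicate number as a block, with an adjusted p = 0.0449, and adjusted p = 0.418 with an estimated correlation. After the correction FTH1 was at 0.58 (adjusted p = 0.00614) and FTL at 0.22 (adjusted p = 0.138). Of 24 other genes of the ATP-binding cassette family, 2 rose, 5 fell and 17 did not pass (list adjusted p = 0.614, and 2 and 5 when adjusted over the list alone). ABCA5 fell with -1.55, the drug exporter gene ABCB1 with -1.17, ABCE1 with -0.73 and ABCC5 with -0.71 ± 0.12 (SE, adjusted p = 0.00122). After the correction 3 were higher and 5 lower.

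The NRF2 oxidative stress list rose. Of 21 members measured, 10 rose, 1 fell and 10 did not pass (adjusted over the list alone, 10 and 2), with a median log2 fold change of 0.35. The list passed with a preset correlation (adjusted p = 0.0054) and after the GC and length correction (adjusted p = 0.0272; 9 higher, 1 lower), but had an adjusted p = 0.821 with an estimated correlation, and 0.426 with both. SRXN1, the sulfiredoxin gene, rose by 1.21 ± 0.14 (SE, adjusted p = 1.33e-04), OSGIN1 by 1.10 ± 0.16 (adjusted p = 6.02e-04), the glutathione peroxidase gene GPX4 by 0.86 and PIR by 0.67. After the correction SRXN1 was at 0.95 (adjusted p = 7.17e-04) and GPX4 at 0.19 (adjusted p = 0.212). The list also passed with shABCB6 1 alone (adjusted p = 0.00469; adjusted p = 0.571 with an estimated correlation) and with shABCB6 2 alone (adjusted p = 0.00494; adjusted p = 0.831 with an estimated correlation).

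The ribosomal protein, oxidative phosphorylation and lysosome and autophagy lists rose, with fewer members past the threshold after the GC and length correction. Of 35 ribosomal protein genes, 27 rose and 0 fell (adjusted over the list alone, 28 and 0; list adjusted p = 3.02e-05, and adjusted p = 0.821 with an estimated correlation), with RPS2 at 0.77, RPLP0 at 0.67 and RPL8 at 0.74. After the correction 8 were higher and 2 lower, and the list was not called (adjusted p = 0.0805). Of 30 oxidative phosphorylation genes, 12 rose and 0 fell, with 18 not past the threshold (adjusted over the list alone, 13 and 0; list adjusted p = 0.00757, and adjusted p = 0.821 with an estimated correlation). CYC1 of complex III rose by 0.81 ± 0.16 (SE), COX5B of complex IV by 0.68, UQCRC1 by 0.65 and NDUFA1 of complex I by 0.70; after the correction 5 were higher and 0 lower (list adjusted p = 0.0622, or 0.0449 with the replicate number as a block too, which an estimated correlation brought to an adjusted p = 0.622). With shABCB6 1 alone 0 members of this list passed, although the list did (adjusted p = 0.0413; adjusted p = 0.868 with an estimated correlation). A block on the replicate number gave 4 higher and 1 lower there, and 3 and 0 after the correction. Of 32 lysosome and autophagy genes, 10 rose, 0 fell and 22 did not pass (adjusted over the list alone, 9 and 0; list adjusted p = 0.0264, and adjusted p = 0.821 with an estimated correlation). HEXA, a lysosomal hexosaminidase gene, rose by 0.52 ± 0.10 (SE), PSAP by 0.56, the cathepsin gene CTSD by 0.75 and the autophagy receptor gene SQSTM1 by 0.64; of 31 with a reference transcript 6 were higher and 0 lower after the correction (list adjusted p = 0.248). Of 12 mitochondrially encoded mRNAs, 2 rose, MT-ND5 by 0.51 and MT-CO1 by 0.75, and 10 did not pass (list adjusted p = 0.332; adjusted over the list alone, 1 and 0; 1 higher after the correction). With the replicate number as a block 6 rose, among them MT-ND2 (0.95, adjusted p = 0.00201) and MT-CO2 (0.57, adjusted p = 0.035), and the list passed (adjusted p = 0.0211; adjusted p = 0.694 with an estimated correlation). These mRNAs took 12.3 ± 2.90% of counts in control libraries, 16.0 ± 2.22% with shABCB6 1 and 16.5 ± 2.38% with shABCB6 2 (SD, n = 3 each), and a larger share in each hairpin library than in the control library of the same number.

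Antigen presentation genes rose as a list. Of 15 measured, 11 rose, 0 fell and 4 did not pass (adjusted over the list alone, 11 and 0), with a median log2 fold change of 0.47 and an adjusted p = 0.00227 for the list; the adjusted p = 0.821 with an estimated correlation. B2M, which encodes beta-2-microglobulin, rose by 0.67 ± 0.12 (SE, adjusted p = 0.00192), HLA-C by 0.62 and HLA-F by 1.09. After the GC and length correction 5 of 14 were higher and 0 lower, and the list had an adjusted p = 0.0622. Correction and replicate block together gave an adjusted p = 0.0449, and adjusted p = 0.418 with an estimated correlation. After the correction alone B2M was at 0.99 (adjusted p = 0.00103). Of 26 extracellular matrix and adhesion genes, 9 rose, 3 fell and 14 did not pass (list adjusted p = 0.087; adjusted over the list alone, 9 and 3), with the integrin gene ITGA5 at 0.82, the cadherin gene CDH3 at 0.82, COL6A2 at 0.85 and ITGA1 at -1.55. After the correction 9 were higher and 2 lower (list adjusted p = 0.0399; adjusted p = 0.482 with an estimated correlation). With shABCB6 1 alone this list rose (adjusted p = 0.00847; adjusted p = 0.737 with an estimated correlation), and with shABCB6 2 alone it was not called (adjusted p = 0.327).

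Cell cycle genes fell as a list, through some of its members. Of 35 measured, 3 rose, 11 fell and 21 did not pass (adjusted over the list alone, 3 and 12); the median was -0.10 and the mean -0.57. The list had an adjusted p = 0.0264, and an adjusted p = 0.821 with an estimated correlation. Besides CENPF and CENPE, the topoisomerase gene TOP2A fell with -1.77 ± 0.11 (SE, adjusted p = 1.28e-06) and the spindle kinesin gene KIF11 with -1.49 ± 0.12 (adjusted p = 6.55e-06). After the GC and length correction 2 were higher and 10 lower (list adjusted p = 0.0272; adjusted p = 0.759 with an estimated correlation), with TOP2A at -1.15 (adjusted p = 6.68e-06) and KIF11 at -0.89.

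The remaining lists were not called by camera in this comparison, while fry passed the NF-kB and MAPK lists (adjusted p = 0.00554 and 0.0413). A pass in fry does not set these lists apart from other genes either. Of 22 p53 target genes, 4 rose and 3 fell (list adjusted p = 0.902; adjusted over the list alone, 3 and 3); GDF15 rose by 0.78, MDM2 fell with -1.13 and TIGAR with -0.72, and 0 were higher and 4 lower after the correction. Of 23 interferon response genes, 3 rose and 6 fell (list adjusted p = 0.601; adjusted over the list alone, 3 and 7); SAMD9 fell with -2.68 ± 0.39 (SE), SAMD9L with -1.84 and ISG20 with -1.27, and IFI6 rose by 0.86 (1 higher and 5 lower after the correction). Of 10 NF-kB and secreted inflammatory genes, 1 rose and 2 fell (list adjusted p = 0.54; adjusted over the list alone, 1 and 2); the cyclooxygenase gene PTGS2 fell with -2.87 ± 0.23 (SE, adjusted p = 7.35e-06) and TNFAIP3 with -0.60, while ICAM1 rose by 0.54 (0 higher and 4 lower after the correction). Of 23 MAPK output and immediate early genes, 2 rose and 4 fell (list adjusted p = 0.605; adjusted over the list alone, 2 and 4); EGR1 fell with -1.38, EGR2 with -1.13 and ETV1 with -0.80, and ETV4 rose by 0.65. After the correction 2 were higher and 5 lower, with EGR1 at -1.65 (adjusted p = 5.73e-04). Of 23 ER stress and ATF4 genes, 1 passed the threshold: the chaperone gene HSP90B1 fell with -1.48 ± 0.10 (SE, adjusted p = 2.06e-06) and was at -1.21 after the correction, while CALR was at 0.54 (adjusted p = 0.0837; with the replicate number as a block, adjusted p = 0.00303) (list adjusted p = 0.673; adjusted over the list alone, 0 and 1; 1 higher and 1 lower after the correction; 6 higher and 1 lower with the block). Of 26 glycolysis and hypoxia genes, 4 rose and 1 fell (list adjusted p = 0.35; adjusted over the list alone, 3 and 1), with GAPDH at 0.64, ALDOA at 0.69 and HK2 at -0.52 (0 higher and 2 lower after the correction; 8 higher and 2 lower with the replicate number as a block). Of 23 cholesterol synthesis genes, PMVK rose by 0.74 and STARD4 fell with -0.89 (list adjusted p = 0.803; adjusted over the list alone, 0 and 0), with a median of 0.05 and a mean of -0.01; 0 were higher and 0 lower after the correction, and 1 higher and 3 lower with the replicate number as a block. Lists with under 5 tested members were described only. The histone genes H4C3 and H1-2 were at 0.83 (adjusted p = 0.283) and 0.29 (adjusted p = 0.528). Of 2 keratinocyte markers KRT10 rose by 0.60 and PERP was at 0.10 (adjusted p = 0.643). After the correction they were at 0.33 (adjusted p = 0.218) and 0.54 (adjusted p = 0.0157). Of 4 fibroblast markers FBLN1 rose by 0.68 and DCN was at 0.71 (adjusted p = 0.246). After the correction they were at 0.37 (adjusted p = 0.0184) and 1.40 (adjusted p = 0.0479). The 1 erythroid or endothelial marker measured, VWF, rose by 1.15 from a control level of 1.62 ± 0.579 CPM (SD, n = 3), and 0 immune cell markers were measured.

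**Figure D4:**
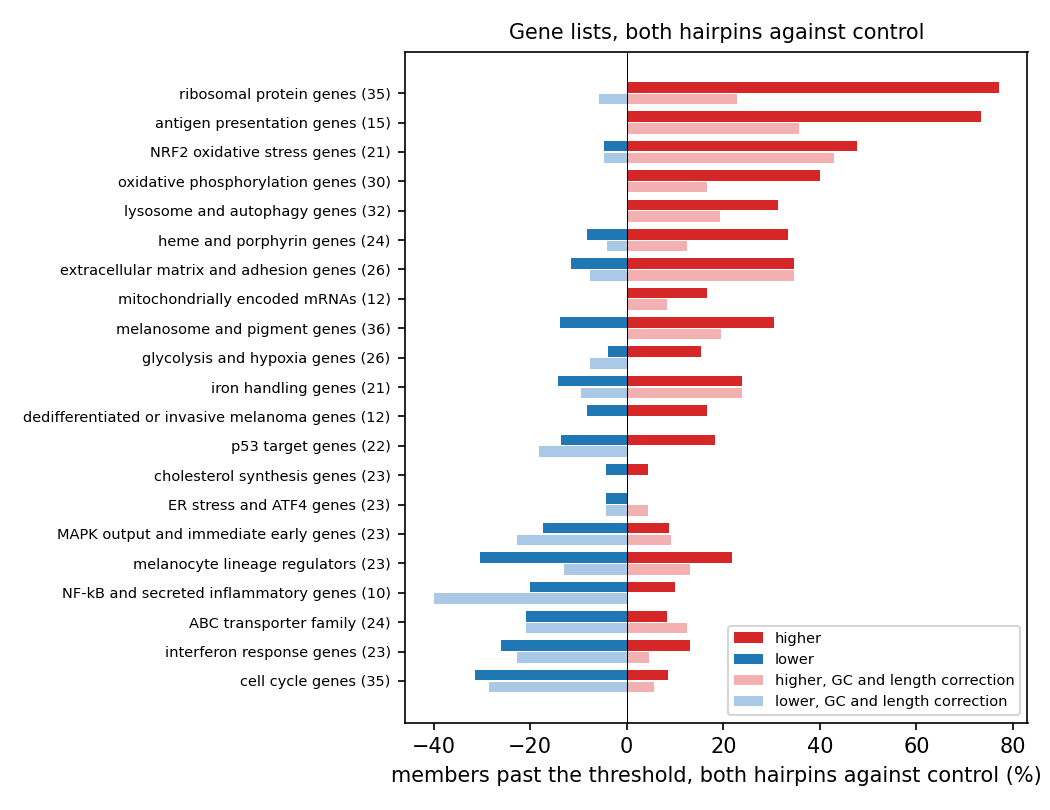
Share of the measured members of each tested list (number in parentheses) past the threshold in both hairpins against control (x axis, %; higher to the right, lower to the left), without (dark) and with (light) the GC and length correction. Ribosomal protein genes drop from 27 to 8 higher members with the correction, whereas NRF2 genes go from 10 to 9.

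shABCB6 1 and shABCB6 2 were compared with each other in the same fit, where the control libraries enter the normalization and the estimate of the spread, and 129 genes passed, 113 higher with shABCB6 1 and 16 lower. Of the 129, 100 were lower with both hairpins than in control, and further with shABCB6 2, and 19 had opposite signs against control. SERPINI1 had the largest difference among the named genes, 2.85 ± 0.22 (SE, adjusted p = 7.02e-04), and was at 0.41 with shABCB6 2 against control (adjusted p = 0.189), or 0.78 after the GC and length correction (adjusted p = 0.0489). The mucin gene MUC7 (2.47), THOC2 of the mRNA export complex (1.96), MAP1B of microtubules (1.96), the cohesin gene SMC3 (1.89) and SLC24A4, a sodium and calcium exchanger of the pigment list (1.83), were also higher with shABCB6 1. MAPK4 (-1.61 ± 0.18 (SE), adjusted p = 0.0064), the amino acid transporter gene SLC38A8 (-1.61), the secreted matricellular gene CCN3 (-1.50), BAG6 (-1.37 and -0.83 for 2 identifiers) and the chromatin protein gene HMGA1 (-1.08) were lower with it. In all 129 genes every library of one hairpin lay beyond every library of the other; 2685 of all tested genes had no overlap, where chance gives 10%. Among lists, ribosomal protein genes (median -0.29, adjusted p = 1.07e-06), oxidative phosphorylation genes (-0.18, adjusted p = 0.0018) and lysosome and autophagy genes (-0.13, adjusted p = 0.0498) were lower with shABCB6 1, and interferon response genes were higher (0.12, adjusted p = 0.0498), although 0 members of these lists passed over all genes; each had an adjusted p = 0.916 with an estimated correlation. The difference also moved with GC content (Spearman rho -0.537 across genes); with the GC and length correction 82 genes passed, 62 higher and 20 lower, and 61 of 125 kept the call. The lysosome and autophagy list lost its call with it (adjusted p = 0.245). Gained calls were those of cholesterol synthesis genes (median 0.36, adjusted p = 0.00374; adjusted p = 0.821 with an estimated correlation) and melanosome and pigment genes (median -0.15, adjusted p = 0.0452; adjusted p = 0.758 with an estimated correlation). The gene count fell to 20 in a fit of these 2 groups alone, to 24 without control replicate 2, to 5 without shABCB6 2 replicate 2 and to 7 without shABCB6 1 replicate 2.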

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

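The tests of the GC and length correction and of A content below were chosen after the results were seen; the others were written before the result they measure. What set these results apart is a difference between the hairpins past the threshold. Between shABCB6 1 and shABCB6 2, 129 genes passed. Among the named genes the log2 difference (shABCB6 1 minus shABCB6 2) was 2.85 for SERPINI1, 2.47 for MUC7, 1.96 for THOC2, 1.96 for MAP1B, 1.89 for SMC3, 1.83 for SLC24A4, 1.58 for RBM25, 1.41 for ABCB6, 1.38 for TOP2A, 0.93 for KIF11 and 0.70 for HSP90B1. It was -0.83 and -1.37 for 2 identifiers of BAG6, -1.08 for HMGA1, -1.50 for CCN3, -1.61 for SLC38A8 and -1.61 for MAPK4. Among lists, the median difference was -0.29 for ribosomal protein genes, -0.18 for oxidative phosphorylation genes, -0.13 for lysosome and autophagy genes and 0.12 for interferon response genes. All 4 lost the call with an estimated correlation (adjusted p = 0.916 each), and the lysosome list also lost it after the GC and length correction (adjusted p = 0.245).

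The 129 genes that differ between the hairpins were mostly genes that fell with both and further with shABCB6 2. Of 125 with a reference transcript, 61 (48.8%) stayed past the threshold after the GC and length correction, and their median absolute difference went from 1.08 to 0.82, so a composition trend that differs between the hairpins and a difference beyond it cannot be told apart for the set: the share lies between the bounds set for each. A larger effect with the deeper ABCB6 knockdown was the explanation the design gives. In the corrected fit 1132 of 1418 genes past the threshold with both hairpins (79.8%) moved further with shABCB6 2, as that explanation predicts. The share does not separate it from off-target effects of single hairpins, which were not tested. Nor does it separate it from a composition bias left after the correction. Before the correction the trend with GC content was stronger with shABCB6 2 (Spearman rho 0.644 against 0.534 with shABCB6 1).

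The 1199 genes that fell with both hairpins were GC-poor and long. In all, 4 explanations were tried, each as the whole cause. A smooth trend on GC content and length is argued against as the whole cause by the 61.0% of the falls that stayed past the threshold after the correction. The falls had a median log2 fold change of -0.86 after the correction in place of -1.24 (71.8% and -0.85 with the replicate number as a block too). The correction removes only such a trend, so it cannot decide on a composition bias of another form. In replicates 2 and 3, 100% of the genes kept at least 50% of their log2 fold change with both hairpins. This cannot decide on the replicate 1 libraries, because the genes were chosen in a fit that already held replicates 2 and 3. The test on A-rich stretches decides nothing, because 80.0% of matched genes have such a stretch and the ratio of 1.06 could not have reached its bound of 1.5; the A content test was added once this was known and the falls were seen to hold 31.2% A against 29.5% in genes matched on GC content, length and expression. With A content in the correction 40.9% stayed past the threshold with both hairpins, 609 genes fell and 1042 were shared in all, and the median was -0.58, so a bias on A content and an effect of ABCB6 knockdown cannot be told apart for these genes.

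The rise of the antigen presentation list could reflect reads split between alternate copies of its members. With the counts of all identifiers of a symbol summed, 13 of 15 members were higher, which argues against it for the members. The list then passed at the preset correlation (adjusted p = 1.4e-05) and not with an estimated correlation (adjusted p = 0.787), as without summing (adjusted p = 0.821). After the GC and length correction the list missed the threshold (adjusted p = 0.0622), while its median went from 0.47 to 0.24, and with the replicate number as a block too the adjusted p was 0.0449 (0.418 with an estimated correlation), so a composition bias stays open for the list, and the knockdown does too.

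Other splits of the same libraries tested whether chance can be excluded. For both hairpins pooled against control, the real split gave 4438 genes and the highest of the other 83 gave 199. Of 84 splits, 1 was as large, the real one. Chance can be excluded for that count if the libraries are independent, which the labels do not say. The count does not tell a hairpin effect from a composition trend that parts the groups. Simulated counts with the GC and length trend of the libraries gave 2059 false calls for both hairpins against control. For genes shared by both hairpins, the real value of 1946 was the only one as large (1 of 100 drawn splits). The highest other, 1744, kept the real control libraries and regrouped the hairpin libraries. All splits that broke up the control group gave 0. The count thus parts the control libraries from the rest. Chance cannot be excluded for the sharing between the 2 hairpins, because regrouped hairpin libraries were drawn with the real controls only 1 other time. The splits of 3 against 3 libraries are too few (10) for a share under 0.05: the real count and the highest other were 2406 and 2 for shABCB6 1, 5217 and 1 for shABCB6 2, and 10 and 1 between the hairpins, and 1 of 10 splits was as large each time. For the gene lists, 62 of 84 splits gave at least the 5 lists of the real pooled split, and the highest other gave 10, so chance cannot be excluded for the number of lists. Splits that part as many same-numbered libraries as the real one give the same reading: the highest other was 199 genes among 27 pooled splits, 1744 among 26 shared ones and 2 and 0 among 4 for shABCB6 1 and shABCB6 2, and 17 of 27 gave at least 5 lists; the splits that part fewer gave at most 14 pooled genes and 0 shared ones.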

How the results depend on the processing

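The direction of ABCB6 and its side of the threshold held in all alternatives run for it, which leave out the fold minimum that its -0.99 with shABCB6 1 misses, with a log2 fold change of -1.07 to -0.89 for shABCB6 1 and -2.58 to -2.29 for shABCB6 2 when 1 library was left out. The GC and length correction, with and without a block, and the fits on replicates 2 and 3 only were added after the data were seen. With an absolute log2 fold change of at least 1 the counts were 776, 1824, 1277, 673 and 78 for shABCB6 1, shABCB6 2, both hairpins, genes shared by both and the difference between hairpins, because fewer genes meet both conditions. The GC and length correction gave 3357 for shABCB6 2, 3306 for both hairpins, 82 between the hairpins and 3 lists for both hairpins. With the replicate number as a block 3424 genes passed for shABCB6 1, 6580 for shABCB6 2, 6207 for both hairpins and 3115 shared; the heme and porphyrin and mitochondrial mRNA lists also passed with shABCB6 1 (adjusted p = 0.0471 and 0.0181) and with shABCB6 2 (adjusted p = 0.0431 and 0.0265), and the lysosome and autophagy list with shABCB6 1 (adjusted p = 0.0471), all lost with an estimated correlation, and of the genes called or not called by name in the main fit only SLX1B, CALR, MT-ND2 and MT-CO2 changed sides in the text; over both hairpins the total of members past the threshold moved by over 1.5 times in 4 lists, where it is given, and the count in one direction in 5 more: NRF2 (1 to 2 lower), oxidative phosphorylation (0 to 1 lower), p53 (3 to 5 lower), interferon (3 to 5 higher) and MAPK (2 to 4 higher). With the block and the GC and length correction together the counts were 3000, 4582, 4641 and 2425, and 3, 7 and 8 lists passed for shABCB6 1, shABCB6 2 and both hairpins. Between the hairpins the same-number correlations of replicates 1, 2 and 3 were 0.368, 0.171 and -0.125, so the pairing was clear there only for number 1. Replicate 2 of shABCB6 1 correlated better with replicate 3 of shABCB6 2 (0.247). In all, 4 of 9 libraries correlated best with their own number in both other groups. With the block 608 genes passed between the hairpins, and 527 with the correction too. The difference between hairpins also gave 194 with no filter, 634 with DESeq2, 48 with limma-voom, 20 in a fit on these groups alone and 213 with replicates 2 and 3; its lists numbered 2 with RLE normalization and 10 with replicates 2 and 3. Camera with an estimated correlation gave 0 lists in each of the 4 comparisons, also with the GC and length correction, the block or both; fry gave 4, 9, 10 and 0. The cause was not tested for any of these. Leaving out 1 library gave 767 to 2677 genes for shABCB6 1 (767, 811 and 951 without control replicate 3, control replicate 2 and shABCB6 1 replicate 3, and 1206 without shABCB6 1 replicate 1), 3586 to 5552 for shABCB6 2 (lowest without control replicate 3), 2829 to 5271 for both hairpins (2829 and 2909 without control replicates 3 and 2) and 726 to 2338 shared (726, 771, 902 and 1153 without control replicate 3, control replicate 2, shABCB6 1 replicate 3 and shABCB6 1 replicate 1). Between hairpins it gave 5 to 170: 24 and 84 without control replicates 2 and 3, 7 and 83 without shABCB6 1 replicates 2 and 3, and 41, 5 and 22 without shABCB6 2 replicates 1, 2 and 3. Its lists numbered 1 without shABCB6 1 replicate 2 and 7 without shABCB6 2 replicate 1, and list counts ran from 4 to 7, 5 to 7 and 5 to 8 in the other comparisons. Of 137 results for named genes past the threshold, 105 stayed past it in the same direction in all settings chosen before the data were examined but the fold minimum, and 92 of 133 did so with the GC and length correction, under which AP3B1 (0.076, adjusted p = 0.678) and ATP7A (0.13, adjusted p = 0.577) changed direction over both hairpins (0.071 and 0.13 with the replicate number as a block too); the cause was not tested. At these depths changes of 1.5-fold were recovered in 14.9% of simulated genes for shABCB6 1, so a gene that did not pass is not shown to be unchanged.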

Other observations

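The families here were chosen after the values were seen, so their counts, for both hairpins against control, are given without a list test. All 6 genes of the SMC family, which hold chromosomes together, condense them or act in their repair, fell, with a median log2 fold change of -3.66, and -2.99 after the GC and length correction. Of 32 genes of the CEP family of centrosome proteins, 20 fell and 1 rose (median -1.23), and 18 were lower and 2 higher after the correction. Of 33 kinesin genes, 16 fell and 4 rose, with 17 lower and 3 higher after it. Of 16 golgin and Golgi tether genes, 8 fell and 1 rose, with 7 lower and 2 higher after it. All 6 GAGE genes measured rose, with a median of 1.59, and 4 were higher after the correction. The genes of these families that fell with both hairpins lie among those for which a bias on A content stays open.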
